A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

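Saccharomyces cerevisiae S288C was grown at 25 °C in rich YPD medium with 2% glucose, 2% polypeptone and 1% yeast extract, per the labels' protocols. Copper sulfate was added to 10 mM at an optical density of 1, and cells were exposed for 2 h, while control cells grew for 2 h without it. PolyA RNA was prepared with hot phenol and an oligo(dT) kit and labelled by first-strand cDNA synthesis with Cy5-dUTP for treated and Cy3-dUTP for control cells, per the labels. All 3 arrays had this dye orientation, so a dye bias of single genes cannot be separated from the effect of copper. The labels describe the 3 arrays as independent biological samples without saying whether each had a control culture of its own, so p-values measure the spread between these arrays.

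The values used were log2 ratios from the authors' deposited table, which were LOWESS-normalized over spots of flag value 0 per the labels. The log base was settled from the values: the lowest value of the table, -6.64 for DEP1 on the high-power scan of replicate 2, equals the log2 of a linear floor of 0.01. DEP1 read 1.17 and 0.03 on the other arrays. The deposited columns had medians of -0.0053, -0.023, -0.025, -0.013 and -0.0017 for the single scan of replicate 1, the high- and low-power scans of replicate 2 and those of replicate 3. Scale and centring are therefore known, and the direction of the ratio is likely rather than stated. Scanner, image software and background treatment are not given in the sources used here.

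Each array was read as 1 replicate, with 5 scans in all. Replicate 1 was its single scan. Replicate 2 was the mean of its high- and low-power scans, or whichever held a value. Replicate 3 was its high-power scan alone, because the series description says that its low-power data were set aside for quality. Values were held by 77.7% of spots on replicate 1, 76.2% and 41.3% on the high- and low-power scans of replicate 2, and 86.1% and 63.2% on those of replicate 3.

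Of 6912 probes, 5446 had 1 gene symbol in the platform annotation used here, 0 had several and 1466 had none. All 5446 gene identifiers were found in the yeast gene table (assembly R64), and 0 symbols changed. As no genome build is named for the array, only names, coding lengths and the order of neighbouring genes were taken from that table, and no coordinates are printed. Only 97.1% of the lengths of tested genes were multiples of 3, so some are not plain coding lengths. Whether these include introns was not checked. Probes of a gene were averaged, giving 5379 genes. The 49 spots of ACT1 held a single repeated value per scan, and 19 other genes had more than 1 probe. Genes without a value on all 3 arrays (555, of which 4 had none) were not tested.

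The mean log2 ratio of 4824 genes was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors after ± are SDs over 3 arrays. Gene lists (36, of which 34 had at least 3 tested members) were tested with camera at its preset correlation of 0.01 and adjusted over the lists. Lists past the threshold are also given camera's adjusted p with an estimated correlation. That form takes its degrees of freedom from the 3 arrays as well, so its adjusted p reflects more than correlation. The symbols ARG5,6 and SLR1 of the lists were not in the gene table. Named genes are the 10 largest mean rises and 10 largest mean falls past the threshold with 1 sign on all 3 arrays, all measured members of the Cup2 and Mac1 lists, and up to 4 members past the threshold with the largest mean change for each list described. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, apart from those named as chosen later.

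The tests were tried on simulated data of 4824 genes in 20 runs, each with 200 genes changed. The gene test recovered 7.91% of genes changed by a log2 of 0.5, 85.7% at 1 and 99.6% at 2, and 4.59% of its calls were false. The list test called a list of 25 genes shifted by 0.5, by its adjusted p, in 20 of 20 runs. Of unshifted lists, 2.25% had an unadjusted camera p under 0.05. The 200 changed genes were a smaller share than the 23.5% of genes called in the data, and recovery under the Benjamini-Hochberg adjustment depends on that share. Simulated genes also varied independently of each other, whereas genes of a real list can vary together, so these rates need not hold for the data.

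Alternatives used other ways of joining scans, all scans as columns with the array as a random block, centring or scaling of arrays, genes with values on at least 2 arrays, removal of DEP1 and ACT1, a robust variance estimate, array weights, a 2-fold minimum, other list tests, and each replicate left out in turn. Chosen after the data were seen were a test that included probes without a gene name, ratios corrected for coding length by a loess fit per array (span 0.4, degree 1), and scans centred within the 8 groups given by the first digit of the probe ID. Explanations were tested in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, using 100000 permutations for single comparisons, 10000 for the orientation of gene pairs and 10000 bootstrap draws for intervals.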

Results

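Budding yeast of the laboratory strain S288C was exposed to 10 mM copper sulfate for 2 h during exponential growth, and its mRNA was set against that of untreated cells on 3 arrays of 2 colours. The labels put copper-treated cDNA in the Cy5 channel and untreated cDNA in the Cy3 channel of every array, and describe the arrays as independent biological samples. The table does not state the direction of its ratios. Treated over untreated is the likely direction, from the order of the channels in the labels, and every rise and fall given here would exchange places under the other one. In earlier work copper induced the CUP1 genes through Cup2 and shut off CTR1 and FRE1 through Mac1, and the likely direction gives those lists, fixed beforehand, medians of 4.25 and -2.78, whose signs the other direction would exchange. Each array carried 6912 spots, of which 5367 on replicate 1, 5264 on the high-power scan of replicate 2 and 5952 on the high-power scan of replicate 3 held a value. The number of arrays limits the precision, and 4824 genes with a value on all 3 arrays were tested.

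The comparison asked which transcripts differ between copper-treated and untreated cells. Genes for copper-binding proteins stood at the top and genes for copper uptake at the bottom. CUP1-1 (YHR053C) and CUP1-2 (YHR055C), near-identical copies of the main copper metallothionein gene, rose to mean log2 ratios of 4.33 ± 1.53 and 4.25 ± 2.12 (SD, n = 3), or 20.1-fold and 19.0-fold. CRS5 (YOR031W), which encodes a further copper-binding metallothionein, rose 8.00-fold (log2 3.00 ± 1.05). FRE1 (YLR214W), the cell-surface reductase that prepares copper and iron for uptake, fell by 3.73 ± 0.36 on the log2 scale, and CTR1 (YPR124W), the high-affinity copper transporter, fell by 3.13 ± 0.95.

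All 3 tested genes of the Cup2 list, the targets of the copper-sensing activator Cup2 (also called Ace1), rose, with the same count adjusted over the list alone. Their median log2 ratio was 4.25, with a camera adjusted p of 0.000892, and an adjusted p = 0.418 with an estimated correlation. Because CUP1-1 and CUP1-2 are near-identical copies, the 3 genes need not be independent measurements. The estimated correlation of this list was 0.962, far above the preset one, so the smaller adjusted p overstates the evidence from the list. SOD1, the copper and zinc superoxide dismutase and the remaining member, held 1.05 and 1.38 on replicates 1 and 2 and no value on replicate 3, so it was not tested. Of the 5 tested genes of the Mac1 list, the targets of the activator of copper uptake, 4 fell and 0 rose, also when adjusted over the list alone, with a median of -2.78 (camera adjusted p = 2.99e-05, and adjusted p = 0.418 with an estimated correlation). The estimated correlation of the Mac1 list was 0.815, again far above the preset one, so its smaller adjusted p overstates the evidence as well. IRC7, which encodes a cysteine-cleaving lyase, and REE1 fell by 2.78 ± 0.25 and 2.24 ± 0.30 beside FRE1 and CTR1. CTR3, a copper transporter gene disrupted by a transposon in many laboratory strains, had -0.17 ± 0.29 (adjusted p = 0.468). FRE7, another surface reductase gene of the list, held -4.09 and -2.54 on replicates 1 and 3 and no value on replicate 2.

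The size of the copper-gene ratios differed between arrays. CUP1-1 read 5.41, 5.002 and 2.57 on replicates 1, 2 and 3, and CUP1-2 read 5.14, 5.78 and 1.83. Without replicate 3 their means were 5.20 and 5.46, that of CRS5 was 3.59, and a correction of the ratios for coding length, chosen after the data were seen, gave 3.59 and 3.51 for the CUP1 genes and 2.34 for CRS5. The call of CUP1-2 was lost with a robust variance estimate (adjusted p = 0.0667), the highest adjusted p of 15 alternatives. Its adjusted p was 0.0121 without replicate 2 (mean 3.48), 1.44e-07 without replicate 3 and 7.65e-42 without replicate 1, the last from a fit whose prior degrees of freedom were infinite, so that all genes shared a single variance.

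**Figure D1:**
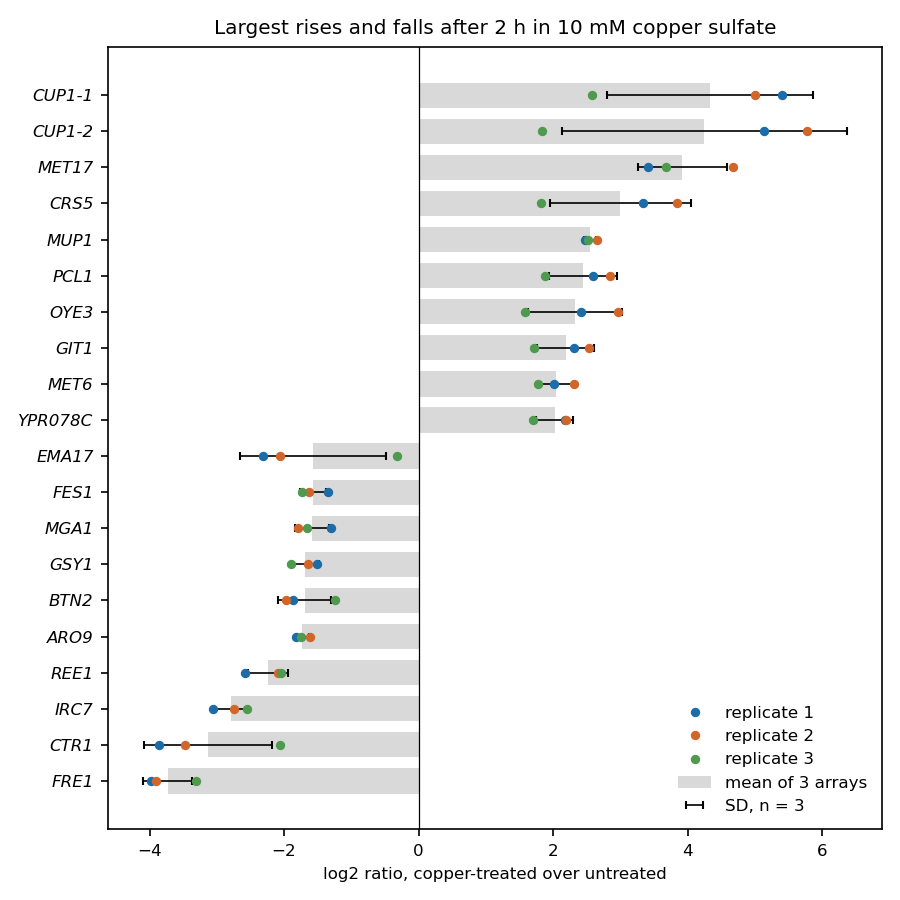
Mean log2 ratios of copper-treated over untreated cells (bars) for the 10 largest rises and the 10 largest falls among genes past the threshold, with the SD of 3 arrays as error bars and each array as a point. CUP1-1 reaches 4.33 and FRE1 -3.73. Of the 3 arrays, replicate 3 lies nearest to 0 for CUP1-1, CUP1-2, CRS5 and CTR1, and also for most other genes shown, though not for MET17, MUP1 or GSY1, for example.

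Genes of sulfate assimilation and sulfur amino acids formed the next large group. MET17 (YLR303W), which joins sulfide to a carbon skeleton to make homocysteine, rose 15.1-fold (log2 3.92 ± 0.66), MUP1, the high-affinity methionine permease, rose 5.85-fold (2.55 ± 0.09), and MET6, methionine synthase, rose 4.11-fold (2.04 ± 0.27). MMP1, the permease for S-methylmethionine, rose 3.09-fold (1.63 ± 0.14). Of 25 tested genes of the list, 15 rose and 0 fell, and 20 rose when adjusted over the list alone. The list median was 0.85 (camera adjusted p = 8.07e-11, and adjusted p = 0.356 with an estimated correlation).

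The other genes among the 10 largest rises were PCL1, a cyclin of the Pho85 kinase (2.44 ± 0.51), OYE3, an NADPH oxidoreductase (2.32 ± 0.70), GIT1, a permease for glycerophosphoinositol (2.19 ± 0.42), and the uncharacterised gene YPR078C (2.02 ± 0.27). The other genes among the 10 largest falls were ARO9, an aromatic aminotransferase (-1.73 ± 0.10), BTN2, a sorting factor for misfolded proteins (-1.69 ± 0.39), GSY1, a glycogen synthase (-1.68 ± 0.20), MGA1 (-1.58 ± 0.25), FES1, an exchange factor of the Hsp70 chaperones (-1.57 ± 0.20), and EMA17 (-1.57 ± 1.08). EMA17 read -2.31, -2.06 and -0.33 on the 3 arrays, had a mean of -2.19 without replicate 3 and was no longer past the threshold without replicate 2 (adjusted p = 0.0603, the highest of 15 alternatives that began at 7.80e-05).

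In the limma test against a ratio of 0, with Benjamini-Hochberg adjustment, 1134 of 4824 genes (23.5%) passed an adjusted p of 0.05, 556 of which rose and 578 of which fell. At least 2-fold changes made up 217 of them, 129 upward and 88 downward. The sign of the ratio was shared by all 3 arrays in 59.4% of genes, against 25% for independent arrays without change, a reference that arrays of a single dye orientation need not meet. With 2 arrays the count depended on which array was left out: 578 genes passed without replicate 1, 494 without replicate 2 and 1211 without replicate 3. The first count is not directly comparable, since the prior degrees of freedom of that fit were infinite and all genes shared a single variance. They were 7.53 without replicate 2 and 9.61 without replicate 3.

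Respiratory genes moved upward as a list. Of 31 tested genes of the respiratory chain and ATP synthase, 12 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.46 and a camera adjusted p of 1.45e-06 (adjusted p = 0.356 with an estimated correlation). The largest changes were those of ATP18 (1.63 ± 0.70), COX9 (1.55 ± 0.41), ATP15 (1.43 ± 0.36) and ATP5 (0.96 ± 0.29), subunits of ATP synthase and, for COX9, of cytochrome oxidase. Ratios corrected for coding length left ATP18 at 0.86, COX9 at 0.79 and ATP15 at 0.70, and took the list mean from 0.49 to 0.24 (adjusted p = 0.00209, the highest of 11 alternatives at the preset correlation, which began at 7.73e-07). In the tricarboxylic acid cycle, 3 of 19 genes rose and 0 fell (6 and 0 adjusted over the list alone), all of them subunits of succinate dehydrogenase: SDH1 (1.06 ± 0.30), SDH2 (1.05 ± 0.08) and SDH4 (0.72 ± 0.41). Its median was 0.25 (camera adjusted p = 0.0280, and adjusted p = 0.418 with an estimated correlation). The call was lost without replicate 3 (adjusted p = 0.0945) and with the low-power scan alone for array 2 (adjusted p = 0.0985), in a range at the preset correlation that began at 0.0125.

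Cell wall genes rose in 15 of 28 cases and fell in 1 (17 and 3 adjusted over the list alone). The mannoprotein genes CWP2 (1.63 ± 0.32) and CWP1 (1.01 ± 0.25), TOS6 (1.59 ± 0.31) and GAS5, a glucan-remodelling enzyme (1.19 ± 0.14), led this list, whose median was 0.54 (camera adjusted p = 2.99e-05, and adjusted p = 0.356 with an estimated correlation). Of 24 tested ergosterol genes, 6 rose and 1 fell, also when adjusted over the list alone. ERG5 (1.02 ± 0.15), ERG3 (0.71 ± 0.22) and ERG28 (0.64 ± 0.13) rose, and ECM22, a transcription factor for sterol synthesis, fell by 0.71 ± 0.22. The list median was 0.29 (camera adjusted p = 0.0252, and adjusted p = 0.389 with an estimated correlation). The ergosterol call was lost without replicate 1 (0.0607) and without replicate 3 (0.0828), in a range of adjusted p at the preset correlation from 0.0118 to 0.0985, and ERG28 was not past the threshold after correction for coding length (adjusted p = 0.0579).

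Cell-cycle genes of several phases also stood higher. Among G1 and S phase genes, 11 of 35 rose and 0 fell, also when adjusted over the list alone, led by PCL1, the repressor gene YOX1 (1.90 ± 0.37), the ribonucleotide reductase gene RNR1 (1.30 ± 0.44) and HCM1, a forkhead transcription factor (1.29 ± 0.22). The median of this list was 0.24 (camera adjusted p = 0.000892, and adjusted p = 0.356 with an estimated correlation). Of 25 genes of G2, M and M/G1, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00211, and adjusted p = 0.380 with an estimated correlation). HST3 (1.15 ± 0.26), PIR3 (0.99 ± 0.27) and the mitotic cyclin gene CLB2 (0.92 ± 0.54) rose, and DSE3 fell by 0.93 ± 0.38. The histone list rose by a median of 0.53, with 6 of 9 genes past the threshold upward and 0 downward (9 and 0 adjusted over the list alone), a camera adjusted p of 0.000267, and adjusted p = 0.356 with an estimated correlation. HTZ1, a variant histone (0.90 ± 0.52), HHO1, the linker histone (0.68 ± 0.11), HHF1 (0.64 ± 0.15) and HTB2 (0.63 ± 0.13) were the largest. Of these 4, HTZ1, HHF1 and HTB2 were not past the threshold once ratios were corrected for coding length, which took the list mean from 0.58 to 0.31 (adjusted p = 0.0252, the highest of 11 alternatives at the preset correlation, which began at 0.000249).

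**Figure D2:**
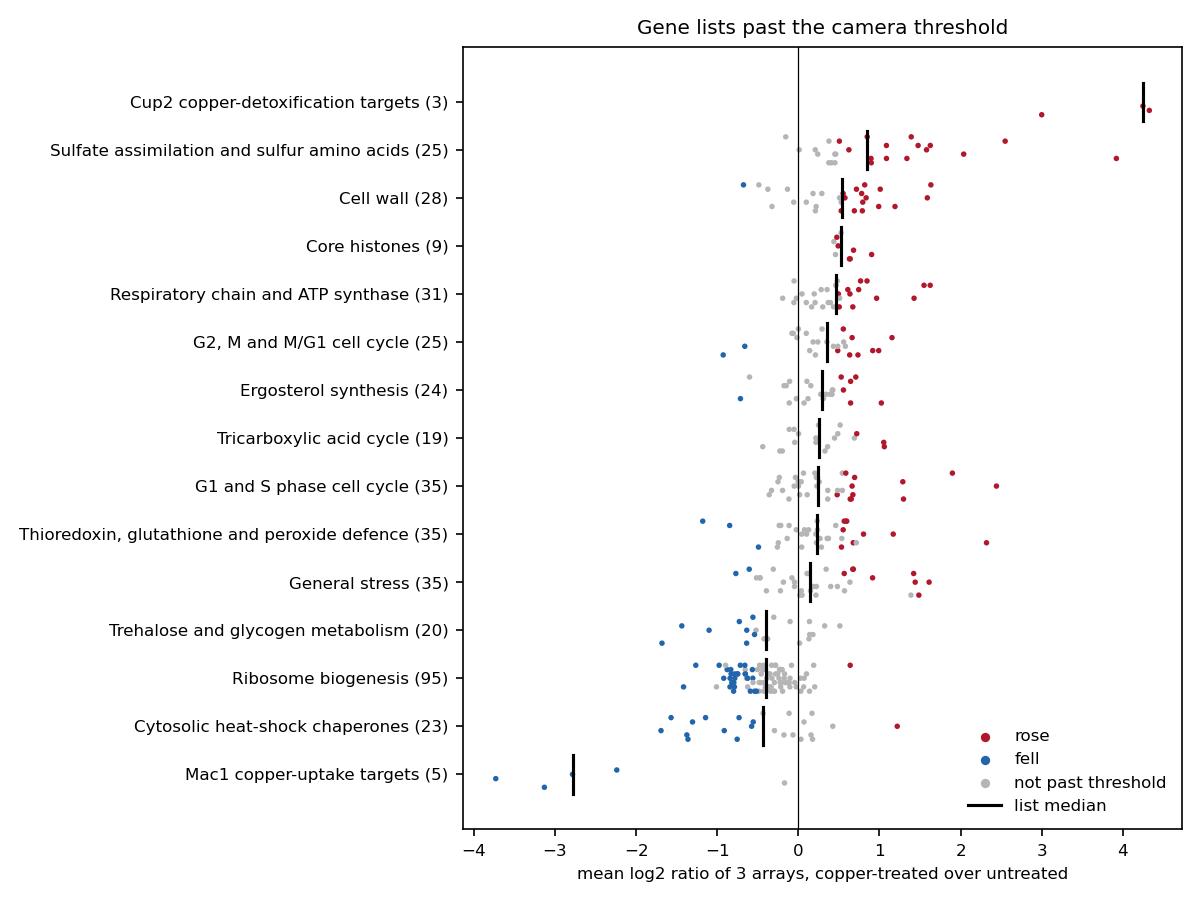
Mean log2 ratio over 3 arrays of every tested member (points) of the 15 gene lists past the camera threshold, with the list median as a black bar and the number of tested members after each name. Red members rose, blue members fell and grey ones were not past the threshold, and the medians run from -2.78 for the Mac1 list to 4.25 for the Cup2 list.

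Cytosolic chaperone genes were lower. Of 23 tested, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.00477, and adjusted p = 0.380 with an estimated correlation). BTN2, FES1, APJ1, a J-domain protein (-1.37 ± 0.19), and HSC82, the constitutive Hsp90 gene (-1.36 ± 0.29), fell the most. Of the genes of trehalose and glycogen metabolism, 8 of 20 fell and 0 rose, also when adjusted over the list alone, and the median was -0.40 (camera adjusted p = 0.0240, and adjusted p = 0.694 with an estimated correlation). GSY1, GLG1, the glycogenin gene (-1.44 ± 0.25), GLC3, the branching enzyme (-1.10 ± 0.47), and PGM2, phosphoglucomutase (-0.73 ± 0.20), fell the most. This call was lost without replicate 2 (adjusted p = 0.0684) and with the length correction (0.0556), in a range at the preset correlation that began at 0.00588.

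Ribosome biogenesis genes fell by a median of 0.40, with 27 of 95 past the threshold downward and 1 upward (30 and 1 adjusted over the list alone), a camera adjusted p of 3.16e-07, and adjusted p = 0.694 with an estimated correlation. NSR1, a nucleolar protein of pre-rRNA processing (-1.42 ± 0.25), RLP24 (-1.26 ± 0.77), ESF1 (-0.98 ± 0.56) and BRX1 (-0.92 ± 0.34) had the largest falls. The list medians were -0.32, -0.76 and -0.16 on replicates 1, 2 and 3. Cytosolic ribosomal protein genes did not move as a group, with 9 of 122 rising and 9 falling (6 and 5 adjusted over the list alone) around a median of -0.02 and a mean of 0.01, which differ in sign (camera adjusted p = 0.648).

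Stress and redox lists held members moving both ways. Of 35 general stress genes, the targets of Msn2 and Msn4, 8 rose and 2 fell, also when adjusted over the list alone, and the median was 0.15 (camera adjusted p = 0.0412, and adjusted p = 0.703 with an estimated correlation). GND2 (1.61 ± 0.87), HSP12 (1.49 ± 0.52), PHM7 (1.44 ± 0.32) and DDR2 (1.42 ± 0.47, or 0.68 corrected for coding length) rose. The call was lost without replicate 1 (adjusted p = 0.0765), without replicate 2 (0.0675) and with the length correction (0.117), in a range at the preset correlation from 0.00301 to 0.245. Of 35 genes of thioredoxin, glutathione and peroxide defence, 9 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0240, and adjusted p = 0.389 with an estimated correlation). OYE3 and GTT2, a glutathione transferase (1.17 ± 0.32), rose, whereas GPX1, a peroxidase gene (-1.18 ± 0.13), and YAP1, the activator of the list (-0.85 ± 0.16), fell. The call of this list was lost without replicate 2 (adjusted p = 0.0513) and with the length correction (0.0670), in a range at the preset correlation from 0.0123 to 0.102.

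Camera with its preset correlation called 15 of 34 tested lists, 11 upward and 4 downward. With an estimated correlation it called 0 lists, 3 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.356. That setting also takes its degrees of freedom from the 3 arrays, so this loss cannot be put down to correlation alone. Core histones and cell wall genes had estimated correlations of -0.118 and -0.011, below the preset 0.01. Their unadjusted camera p still went from 4.72e-05 to 0.0515 and from 3.82e-06 to 0.0349. Other lists lay above the preset, such as ribosome biogenesis at 0.434. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, called 8 lists, 7 of them among the 15: Mac1, chaperones, sulfur, respiratory chain, histones, G1 and S phase, and cell wall. The eighth was the list of mitochondrial copper delivery and cytochrome oxidase assembly (fry adjusted p = 0.0429, median 0.24), which camera did not call (adjusted p = 0.142) and whose mean went from 0.18 to 0.02 with the length correction (camera adjusted p = 0.726).

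Metal regulons other than copper did not pass the list test. In the iron regulon, 9 of 24 genes rose and 5 fell (10 and 7 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.173). FTR1, the iron permease (1.33 ± 0.22), ISU2, a scaffold for iron-sulfur clusters (1.21 ± 0.35), and FIT1, a cell-wall protein that retains siderophores (1.10 ± 0.26), rose, whereas SIT1, a siderophore transporter (-1.39 ± 0.17), fell. In the zinc regulon, 1 of 14 genes rose and 3 fell (2 and 4 adjusted over the list alone; median -0.07, camera adjusted p = 0.786). ZPS1 (-0.84 ± 0.51) fell, with -1.42, -0.59 and -0.49 on replicates 1, 2 and 3, and ZAP1, the activator of that regulon (0.59 ± 0.29), rose.

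Ratios also differed with gene length. Among the 487 genes of shortest coding length (median 384 bases), 148 rose and 27 fell, and the median log2 ratios were 0.36, 0.37 and 0.14 on replicates 1, 2 and 3. Among the 483 longest genes (median 3276 bases), 22 rose and 59 fell, with medians of -0.08, -0.22 and -0.02. Across genes, Spearman's rho between coding length and the mean log2 ratio was -0.162.

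**Figure D3:**
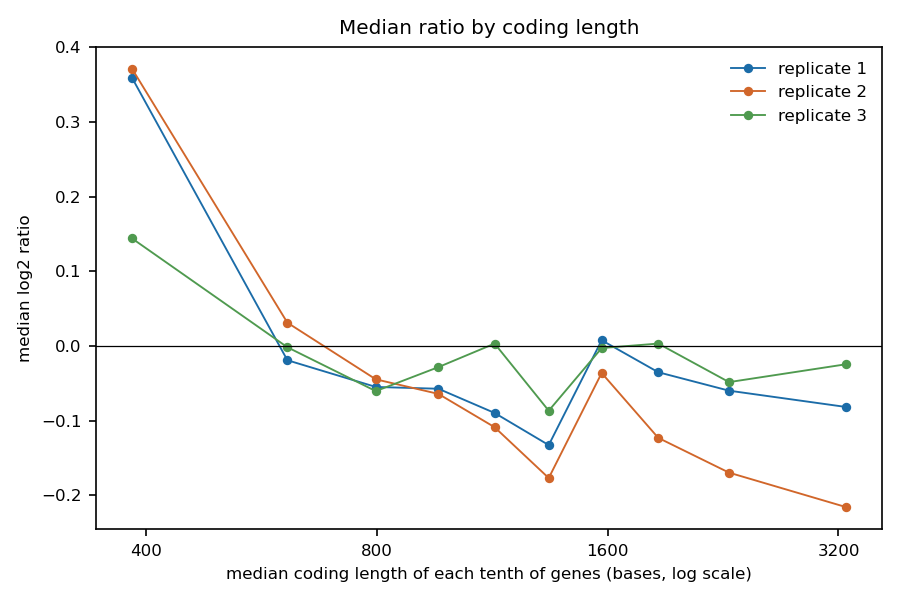
Median log2 ratio of copper-treated over untreated cells in 10 groups of genes of rising coding length, against the median coding length of each group in bases on a log axis, with 1 line per array. The shortest group, at 384 bases, lies at 0.36, 0.37 and 0.14 on replicates 1, 2 and 3, above every other group of the same array.

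The arrays ranked genes alike but not identically. Across the 4824 genes, which are not independent replicates, Pearson's r was 0.693 between replicates 1 and 2, 0.651 between replicates 1 and 3 and 0.606 between replicates 2 and 3, and Spearman's rho was 0.681, 0.631 and 0.565. The high- and low-power scans of 1 array agreed more closely, with r = 0.937 over 2671 genes on array 2 and r = 0.874 over 4072 genes on array 3. The SD of the log2 ratios across genes was 0.58, 0.66 and 0.48 on replicates 1, 2 and 3.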

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

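Chosen only after the result was seen were the tests of a single scale and of saturation on array 3, of gene length itself, and of turned arrays, as well as the settings with unnamed probes, the length correction and the centring by probe ID. Probes without a gene name in the annotation used here lay outside every comparison. Tested together with the named genes, 76 of 252 such probes with a value on all 3 arrays passed the threshold (30.2%), of which 67 rose and 9 fell, 18 of them by at least 2-fold.

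Several of the largest ratios were smaller on replicate 3: for CUP1-1, CUP1-2, CRS5, CTR1 and OYE3, picked after their values were seen, the median ratio of replicate 3 to the mean of replicates 1 and 2 was 0.508. A single scale for the whole array, as the only cause, is argued against by its scale over array 1, from covariances across genes, which was 0.601 for the 2138 genes without a value in the low-power scan of array 2 and 0.824 for the 2686 with such a value (difference -0.2229, 95% bootstrap interval -0.287 to -0.155; over array 2 the difference was -0.198, interval -0.257 to -0.132), a test that replaced an earlier comparison with 5 genes picked by their ratios (median 0.881). Over all genes the scale of array 3 was 0.723 over array 1 and 0.678 over array 2, while that of array 2 over array 1 was 1.07. A smaller scale of array 3 as a whole may therefore contribute, and the test shows only that it was not uniform. Saturation of the high-power scan is argued against, though only weakly, by the low-power scan of array 3, which was set aside for quality and held no value for CRS5. Its log2 ratios were larger in size by a median of only 0.0021 over the 4 of the pattern's genes that it measured, with gains from -0.196 for OYE3 to 0.061 for CTR1. A candidate explanation that stays open is that dim spots lose contrast on array 3: among genes at least 2-fold in 1 direction on both other arrays, the median ratio was 0.532 for the 101 genes without that low-power value and 0.793 for the 98 with it (difference -0.2612, permutation p = 1e-05, the smallest that 100000 permutations can give), while the same difference was 0.018 for array 1 and 0.228 for array 2. Of the 20 largest changes, the 12 without the low-power value, which include all 5 genes of the pattern, had ratios from 0.149 (EMA17, lower than any of those 5 and left out when they were picked) to 0.909 and the 8 with it from 0.842 to 1.21, and a smaller response of the third culture was not tested. Lacking that value need not mean a dim spot. The highest log2 ratio of the low-power scan of array 2 was 2.66, against 5.78 on its high-power scan. Genes with the largest rises were therefore absent from the group with a value, and the grouping cannot tell dim spots from large rises.

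The shortest genes had higher ratios. The tenth of genes with the shortest coding length (487 genes, median 384 bases) had a median log2 ratio of 0.27, with 148 rises and 27 falls, against medians from -0.15 to 0.0028 in the other 9 groups of this size. Low signal is argued against by the 255 shortest genes with a low-power value on array 2, whose median was 0.4508 (95% bootstrap interval 0.368 to 0.483), and membership in lists that rose is argued against by the 355 shortest genes in none of the lists, with a median of 0.2588 (0.179 to 0.342). The 232 shortest genes without a low-power value on array 2 had a lower median, 0.107. In the other 9 groups together the medians were -0.151 without such a value and -0.012 with one. A technical effect of length itself cannot be told apart from a change of these transcripts: 21 short ribosomal protein genes differed from the other shortest genes by -0.06128 (interval -0.22 to 0.07, two-sided permutation p = 0.725), too wide to decide, under a criterion tightened after the value was seen. The comparison and the length correction are further limited because lengths that include introns, which would misplace such genes, were not excluded. Corrected for coding length, 1042 genes passed, and 5 genes called before changed sign without being past the threshold (OST4, HOR7, HUG1, CPP3 and RPS29A, named after their values were seen).

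Neighbouring genes had similar ratios. Across 3884 pairs of adjacent tested genes, leaving out the CUP1 locus, Pearson's r of the mean log2 ratios was 0.137 (Spearman's rho 0.136, permutation p = 1e-05, the smallest possible), a correlation over genes, which are not independent. Neighbouring spots on the array stay open: r was 0.167 for 383 pairs whose probe IDs start with the same digit and 0.1337 for 3501 pairs with different first digits, a bound set beforehand to count against them, but no file says that this digit marks a place on the array, so the bound was wrong. Shared promoters may contribute, since r was 0.190 for 992 divergent pairs, 0.144 for 1855 tandem pairs and 0.0691 for 1037 convergent pairs, but the excess of divergent pairs over the others, 0.07088, had a permutation p of 0.0614 and leaves this open.

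Turning the sign of 1 array at a time gives 4 choices with the real one, of which 1, the real one, reached 1134 genes, and the highest of the others was 0. These are too few choices for a share under 0.05.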

How the results depend on the processing

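Chosen after the data were seen were the settings with unnamed probes, the length correction and the centring by probe ID. No paired analysis was possible because there is 1 group, and each ratio already sets treated against untreated cells on 1 array. Signal over background is not in the table, so the limit set by dim spots could not be measured. Over 17 settings the count of changed genes ranged from 217 with a 2-fold minimum (129 up, 88 down) to 1616 with array weights, and of the 1134 calls that could be tested again 5 changed sign under the length correction and 0 under each of the other 16. Some of these settings, such as the 2-fold minimum and the robust variance estimate, left the means of called genes as they were and could not change a sign. Of the 1134 calls, 530 were kept without replicate 1, 470 without replicate 2 and 928 without replicate 3. With the low-power scan alone for array 2, 2686 genes were testable, 442 rose, 349 fell and the mean correlation of arrays was 0.706 against 0.650. The latter value is over the 4824 genes of the main test, so the scans are not compared on the same genes. Leaving out 1 array gave 494 to 1211 genes, 276 to 573 up and 218 to 638 down, and 12 to 16 lists. With an estimated correlation 0 lists passed, and 8 passed by fry. Of 130 named genes tested, 31, 43 and 12 lost their call without replicates 1, 2 and 3, and 10 with the length correction, the most of any other setting. The fit without replicate 1 gave all genes a single variance, so its counts are not directly comparable with those without replicates 2 and 3. Centring the arrays took the split from 556 up and 578 down to 631 and 502.

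List means that changed sign belonged to lists not past the threshold, and the cause was not tested. With the low-power scan alone they were hexose transporters -0.19, gluconeogenesis -0.095, autophagy 0.45, vacuolar ATPase 0.019 and haploid genes 0.12. Glycolysis turned to 0.035 with both scans of array 3, 0.0076 with centring and 0.0048 with scaling as well, and autophagy to 0.023 and 0.0196. The length correction turned ribosomal proteins to -0.073. Leaving out each array, hexose transporters ranged from -0.051 to 0.188, ribosomal proteins from -0.056 to 0.071, autophagy from -0.027 to 0.00077, the vacuolar ATPase from -0.131 to 0.032, Gcn4 genes from -0.040 to 0.053 and gluconeogenesis from -0.0052 to 0.045.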

Other observations

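In the remaining lists, which did not pass the list test, single genes passed the threshold. Among multidrug transport genes, 4 of 22 rose and 1 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0888). The polyamine exporters TPO4 (1.59 ± 0.11) and TPO1 (1.09 ± 0.40) rose. Of 35 genes of the 26S proteasome, 7 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0614), with RPN8 at -1.42 ± 0.40 and UMP1, a proteasome assembly chaperone, at 0.78 ± 0.42, the latter no longer past the threshold after the length correction (0.56, adjusted p = 0.0768). Mitochondrial chaperones went both ways (1 of 10 rose and 3 fell, also when adjusted over the list alone, camera adjusted p = 0.859): HSP10 rose (1.10 ± 0.20, or 0.71 and still past the threshold after the length correction), and MGE1 (-0.93 ± 0.32) and HSP78 (-0.92 ± 0.40) fell. Of 24 DNA damage genes, 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.710), with RNR1 at 1.30 and the photolyase gene PHR1 at -1.23 ± 0.16.

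In the hexose transporter list, 1 of 15 genes rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.710), with HXT2 at -1.08 ± 0.56. Glycolysis and fermentation had 1 fall, ADH3 (-0.59 ± 0.23), and 0 rises among 16 genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.983). In amino acid synthesis under Gcn4, 3 of 38 genes rose and 2 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.698). Translation factors had 6 falls and 1 rise among 35 genes, also when adjusted over the list alone (camera adjusted p = 0.0614), and mitochondrial ribosomal proteins 6 falls and 4 rises among 70 (3 and 3 adjusted over the list alone; camera adjusted p = 0.374). Endoplasmic reticulum folding genes had 3 rises and 0 falls among 21 (0 and 0 adjusted over the list alone; camera adjusted p = 0.0614). The list of mitochondrial copper delivery and cytochrome oxidase assembly had 2 rises, SCO1 (0.61 ± 0.22) and COX10 (0.54 ± 0.29), and 1 fall, SCO2 (-0.51 ± 0.12), among 12 genes, also when adjusted over the list alone (camera adjusted p = 0.142, fry adjusted p = 0.0429, list mean 0.02 after the length correction).

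Some of these lists passed under other settings. Among alternatives at the preset correlation, the proteasome list passed in 4 of 11 (lowest adjusted p 0.0173), translation factors in 4 of 11 (0.0233), endoplasmic reticulum folding in 3 of 11 (0.0426), meiosis genes in 2 of 10 (0.0227), multidrug transport in 1 of 11 (0.0321) and mitochondrial ribosomal proteins in 1 of 11 (0.0273).

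Of 18 gluconeogenesis genes, 1 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.710), with the ammonium exporter gene ATO3 at -1.04 ± 0.13. Of 22 autophagy genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.991), with ATG22, a vacuolar amino acid exporter, at 1.26 ± 0.26 and ATG20 at -1.02 ± 0.56. The vacuolar H+-ATPase had 2 falls and 0 rises among 17 genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.912), with a median of 0.04 and a mean of -0.07.

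Of 15 haploid and pheromone genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.632), and of 9 tested meiosis genes of 30, 3 rose and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0646), led by the spore wall gene SPS100 (1.54 ± 0.50). The lists specific to MATa and MATalpha cells had 2 tested members each and were not put to the list test: 0 of the MATa genes passed, also when adjusted over the list alone, and of the MATalpha genes MF(ALPHA)2 fell (-0.78 ± 0.17), with 0 rises and 2 falls adjusted over the list alone (median -0.61).

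YHR054C, which lies between CUP1-1 and CUP1-2 in the gene table and was chosen after its value was seen, rose 3.86-fold (log2 1.95 ± 0.34, adjusted p = 0.00105, higher in 3 of 3 arrays).

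The first digit of the probe ID accounted for 7.48% of the variance of log2 ratios on the high-power scan of replicate 3, against 1.34% on replicate 1 and 0.955% on the high-power scan of replicate 2. The medians of its 8 groups ran from -0.17 to 0.23 on that scan of replicate 3.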
